A study of Arabidopsis thaliana with 2 samples.

How the data were processed

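Total RNA from whole Arabidopsis thaliana plants (leaves and roots) of the Columbia (Col) background was labelled with biotin and hybridised to Affymetrix ATH1 arrays. There were 2 arrays, 1 of control plants and 1 of plants grown with Trichoderma hamatum, and each was assigned to its group from its title. Both were labelled as replicate 1, so neither group had a replicate. The precision of every value is limited by this number of arrays.

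The deposited table held 1 intensity per probe set and array, and the range of the values is that of a linear scale. Per the submitters' processing notes, the values were made with MAS5, an Affymetrix algorithm that reduces the probes of a probe set to a single signal. Its version and parameters are not given in the sources used here. The mean of each array without the lowest and highest 2% of its 22810 values was 100, so the arrays had been brought to the same level before deposit. Detection calls were not analysed here, and the scanner files were not used here.

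The 64 Affymetrix control probe sets were set apart, which left 22746 probe sets for the plant. Genes were named from a platform annotation and a reference gene table (assembly TAIR10.1). The annotation gave 1 gene for 13513 probe sets and several genes for 503, and it left 8730 unnamed here. Of the probe sets with 1 gene, 13436 matched the reference gene table and 77 kept the name in the annotation. Probe sets with several genes were counted but never named. Because the sources name no genome build, no coordinates are given.

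A floor at the 40th percentile of each array stood in for detection calls. It lay at a signal of 25.2 on the control array and 24.5 on the T. hamatum array, and a probe set above it on both arrays is called measured. The log2 ratio was the log2 signal of the T. hamatum array minus that of the control array, centred on its median over the measured probe sets. That median was 0.004 in the deposited values. Probe sets with a ratio of 2-fold or more were counted. A probe set at or above the 75th percentile of one array and at or below the floor of the other was given only a bound, the bright signal over the dim array's floor, with the same centring as the ratios. With 1 array per group there was no test, and no p-value or standard error is given.

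Before the data were examined, 25 gene lists with 494 entries were fixed. Of these entries, 6 were dropped because the reference table gave their locus another symbol, 68 had a probe set that named their locus alone, and 53 were measured. Probe sets of a locus were averaged. Of 6912 measured loci, 63 had more than 1 probe set, and the log2 ratios of a locus then differed by a median of 0.21. They differed by 1 or more at 2 loci, AT2G38840 (-0.69 and 0.68) and AT4G16180 (0.71 and -0.31), which were singled out after their values were seen. For each list with at least 3 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from the measured loci and matched on mean log2 level in 20 bins. Such a percentile describes these 2 arrays and is not a test of the conditions. The rule for named genes was fixed at the same time. It took the 12 highest and 12 lowest log2 ratios among measured probe sets with 1 gene and a mean level at or above the median, up to 3 bounded probe sets per direction, and from each list the up to 2 highest and 2 lowest members with those past 2-fold, at most 4 of which were printed each way. A further 11 genes were to be given whatever their values, and 10 of them (PR1, PR2, PR5, VSP2, LOX2, MYB72, NRT2.1, CHS, CCA1 and TOC1) were not analysed here, since the annotation used lists no probe set under their names alone.

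The alternatives were the deposited values without centring, quantile normalization, removal of a lowess trend (fraction 0.3) of the ratio on the level, floors at the 25th and 60th percentiles, 16 added to each signal before log2, and the highest probe set of a locus in place of the mean. Restriction to probe sets with 1 gene, and a further 15 gene groups, were added after the annotation had been seen. The result of 1 of these groups is not reported here. The comparison was tested on simulated data made from these arrays, with 13186 measured probe sets, in which 200 probe sets were changed by 1.5 on the log2 scale. It found 97% of the changed and measured probe sets at 2-fold or more, and an added shift of 0.30 between the arrays was found as 0.30. Centring finds a constant shift by design. The changed probe sets were drawn from those of higher mean level, and large noise values were capped. The 97% therefore does not cover dim probe sets. Of the unchanged measured probe sets, 0.870% also passed 2-fold. The simulated noise was drawn from the observed ratios with random signs, so this share carries over any real differences and does not measure the rate of false calls, which cannot be had without replicates. Of 200 simulated lists without a change, 5.5% lay outside the 95% range. Their members were drawn at random from the loci that the random lists came from, so a share of this size was built in. It does not show how often lists of related genes would lie outside. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.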

Results

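Transcript levels were compared between Arabidopsis plants grown on compost with the soil fungus Trichoderma hamatum and control plants grown without it. The series asks how this fungus promotes plant growth. Whole plants at the same labelled growth stage, from a growth room with a 16 h photoperiod, were profiled on 1 ATH1 array per group. Median signals were 41.7 on the control array and 40.3 on the T. hamatum array, and 13182 of the 22746 plant probe sets (58.0%) were above the floor on both. There were no replicates, so no difference could be set against a spread between plants.

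Most probe sets that differed by 2-fold or more had lower signals in plants grown with T. hamatum than in controls. Of the measured probe sets, 106 were at least 2-fold lower and 12 at least 2-fold higher, while 13064 (99.1%) lay within 2-fold. At 4-fold or more, 11 were lower and 0 were higher. A further 6 probe sets were bright on the control array and at or below the floor with T. hamatum, and 0 showed the opposite. These counts depended on the floor and on dim signals. There were 193 lower and 51 higher with the floor at the 25th percentile, 47 and 7 at the 60th, and 58 and 6 with 16 added to each signal. The central 95% of log2 ratios ran from -0.65 to 0.49. Log2 signals of the arrays had a Pearson correlation of 0.980 across probe sets, which are not independent replicates.

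PDF1.2 (AT5G44420), an antifungal peptide gene used as a marker of combined jasmonate and ethylene signalling, had a signal of 1388 in controls and 88.3 with T. hamatum, which is 15.8-fold lower and the lowest log2 ratio measured (-3.98). Its close relative PDF1.2b (AT2G26020) was 10.8-fold lower (1786 against 166). That probe set carries the suffix for probes shared between similar transcripts, so its signal may include PDF1.2. EIN3, the other measured gene of the ethylene list and a transcription factor of ethylene signalling, differed by a log2 ratio of -0.16.

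The calmodulin-like gene CML38 (AT1G76650) went from 262 to 17.7, below the floor, and was thus at least 10.7-fold lower. AT3G01830, which encodes another calmodulin-like protein, was at least 5.99-fold lower (147 against 16.2). The zinc finger repressor STZ, also called ZAT10 (AT1G27730), was 2.89-fold lower, and the U-box ubiquitin ligase PUB19 (AT1G60190) was 2.81-fold lower. Others among the 12 lowest were AT1G15010 (8.61-fold), AT2G27080 (6.36-fold), AT4G29780 (4.52-fold), AT1G74450 (4.15-fold) and AT4G24380 (2.24-fold). The jacalin-type lectin genes AT1G52060 and AT1G52070 were 3.75-fold and 2.47-fold lower.

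**Figure D1:**
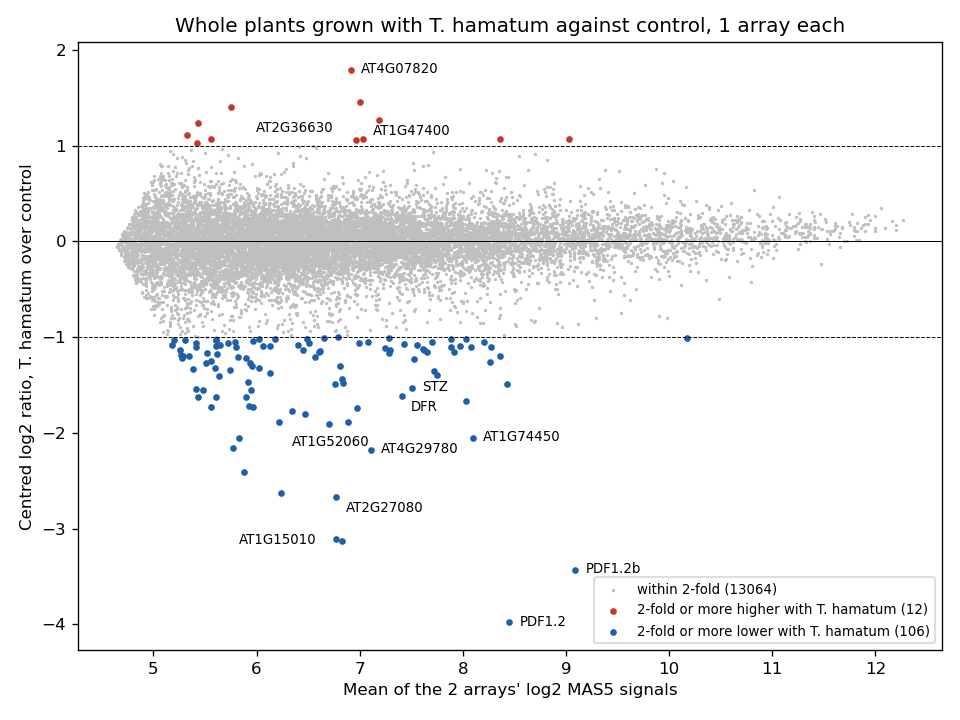
Centred log2 ratio (T. hamatum over control, vertical axis) of each of the 13182 measured probe sets against the mean log2 MAS5 signal of the 2 arrays (horizontal axis); each point is a probe set, and dashed lines mark 2-fold. Blue points (106 probe sets at least 2-fold lower) outnumber red points (12 at least 2-fold higher), with PDF1.2 lowest at -3.98; gene names mark 12 of the probe sets the naming rule selected.

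Fewer genes were higher with T. hamatum, and by smaller factors. The highest was AT4G07820, which encodes a protein of the CAP family, at 225 against 64.9 (3.45-fold). AT1G47400, an IRON MAN peptide gene known to accumulate under iron deficiency, had a log2 ratio of 1.07 (190 against 90.0), and AT2G36630 was 2.08-fold higher. The other 9 of the 12 highest were under 2-fold. Among them were the arsenate reductase gene AT2G21045 (1.80-fold), AT3G15570 (1.77-fold), the peroxidase gene AT3G01190 (1.73-fold), AT4G16180 (1.64-fold) and AT1G18810 (1.59-fold). AT4G16180 had another probe set, which was lower with T. hamatum (log2 ratio -0.31), so its direction is not settled. The remaining ones were AT3G07350 (1.59-fold), AT2G44380 (1.59-fold), the lipid transfer protein gene AT5G01870 (1.58-fold) and AT1G55960 (1.57-fold). With 16 added to each signal, AT1G47400 and AT2G36630 lay at log2 ratios of 0.95 and 0.93, under 2-fold.

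In the phenylpropanoid and flavonoid list, 3 of 4 measured members were at least 2-fold lower and 0 were higher. These were the anthocyanin glucosyltransferase UGT75C1 (3.08-fold), dihydroflavonol reductase DFR (3.06-fold) and the anthocyanin glycosyltransferase UF3GT (2.12-fold). UGT78D2, which glycosylates flavonols as well as anthocyanins, had a log2 ratio of -0.07. The list's median was -1.35, below those of all 10000 matched random lists (percentile 0), whose central 95% ran from -0.28 to 0.22. The list had 22 entries, of which 4 could be measured. UF3GT was under 2-fold (log2 ratio -0.91) with 16 added to each signal.

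The early pattern-triggered and touch response list had a median log2 ratio of -0.96, at percentile 0.015 of matched random lists (95% range -0.36 to 0.33). Of its 19 entries, 3 were measured. These were all transcription factors of stress responses and had values below 0. ZAT10 was at -1.53, WRKY22 at -0.96 and WRKY53 at -0.48, and 1 of them passed 2-fold. WRKY22 had low signals of 48.9 in controls and 25.1 with T. hamatum, close to the floor. In the salicylic acid list, 2 of 21 entries had a named probe set. The glutaredoxin GRX480 (AT1G28480) was 2.51-fold lower (103 against 41.1), and SAG101 was not above the floor on both arrays (31.8 and 23.7). The only jasmonate entry with a named probe set, the thionin THI2.1, was below the floor on both arrays (10.7 and 10.6).

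Of 5 chitinase and glucanase list members with a named probe set, 3 were measured. These were AT2G43590 (log2 ratio 0.33), AT2G43610 (0.14) and AT2G43570 (0.13), and the median of 0.14 was at percentile 83.3. AT2G43580 (5.86 in controls and 2.07 with T. hamatum) and AT2G43620 (19.2 and 14.9) were below the floor on both arrays. The aliphatic glucosinolate list had a median of 0.19 (percentile 89.9), with UGT74C1 at 0.37, BCAT4 at 0.19 and GSTU20 at 0.01, the last of these turning to -0.04 after quantile normalization. GSTU25, the single measured gene of the oxidative stress list, was at 0.04.

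Among lists related to growth, the cell wall list had a median log2 ratio of -0.23, which corresponds to 1.17-fold lower and lay at percentile 1.75 (95% range -0.21 to 0.21). Of its 23 entries, 5 were measured, and 0 of these reached 2-fold. The expansin EXPA4 was at -0.56, the xyloglucan endotransglucosylases XTH19 and XTH18 at -0.26 and -0.18 and XTH16 at 0.22, while XTH33 was not above the floor. The auxin list had a median of -0.04 (percentile 37.9), or -0.29 (percentile 5.56) with the floor at the 25th percentile and 4 members measured. It held the auxin-conjugating enzyme GH3.5 at -0.55, IAA29 at -0.04 and LBD16 at 0.09. IAA29 (27.8 in controls and 27.1 with T. hamatum) and LBD16 (25.4 and 27.1) had signals close to the floor. GH3.3, another auxin-inducible conjugating enzyme, had a signal of 58.5 in controls and 11.0, below the floor, with T. hamatum. It therefore did not enter the median of -0.04. GH3.1 and LBD29 were below the floor on both arrays. The 4 measured genes of the cytokinin, gibberellin and brassinosteroid list had values below 0 (median -0.22, percentile 6.93). They were GID1A (-0.26), GID1B (-0.23), ARR15 (-0.22) and ARR16 (-0.05, or 0.01 after quantile normalization). In the cell cycle list, MCM7 was at 0.13, AUR1 at 0.02 and AUR2 at -0.26, with a median of 0.02 (percentile 58.9), or 0.06 after quantile normalization.

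**Figure D2:**
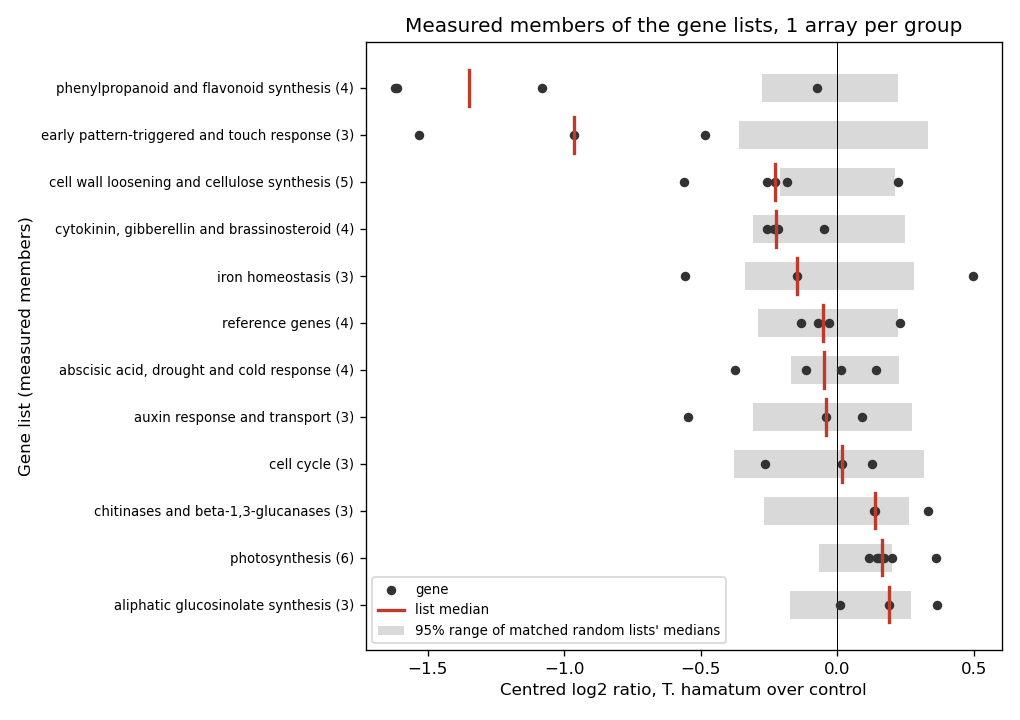
Centred log2 ratios (T. hamatum over control, horizontal axis) of the measured members of each list with at least 3 of them; points are genes, red bars list medians, and grey bands the central 95% of the medians of 10000 matched random lists. The medians of the phenylpropanoid and flavonoid list (-1.35), the early response list (-0.96) and the cell wall list (-0.23) lie outside their bands, and the other 9 lie inside.

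Of the 38 entries of the photosynthesis list, 6 were measured. These had log2 ratios above 0, from LHCB4.1 at 0.12 to the Calvin cycle enzyme SBPASE at 0.36. PSAE1 was at 0.20 and Rubisco activase (RCA) at 0.14. The list's median of 0.16 was inside the range of equally bright random lists (percentile 93.0, 95% range -0.07 to 0.20). It was 0.04 after quantile normalization and 0.07 without the lowess trend, where LHCB4.1 was at 0.00 in both. The iron list had a median of -0.15 (percentile 15.9), which turned to 0.18 (percentile 92.3) with the floor at the 25th percentile and 4 members measured. In it the iron-deficiency regulator PYE was at 0.50, the coumarin synthesis enzyme F6'H1 at -0.15 and the glucosidase BGLU42 at -0.56. BHLH101 was at 24.1 in controls and 39.7 with T. hamatum. The abscisic acid, drought and cold list had a median of -0.05 (percentile 19.1), with COR15B at 0.14, COR15A at 0.01, LTI30 at -0.11 and COR47 at -0.37. Of the clock list only GI was measured, at 0.10.

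Markers of organs and cell types, which show whether the plant samples held like shares of root and shoot, gave few values. PYK10, an abundant root beta-glucosidase, was at 2291 in controls and 2669 with T. hamatum (1.16-fold higher). The root hair expansins EXPA7 and EXPA18 had signals of 39.7 and 38.1 in controls and 21.1 and 21.6, below the floor, with T. hamatum. Of the stomatal lineage genes, FAMA was at a log2 ratio of 0.26, and SPCH and MUTE were below the floor on both arrays. The senescence-associated WRKY6 was at -0.34 and SWEET15 was below the floor on both arrays. The reference genes TIP41 (0.23), F-box gene AT5G15710 (-0.03, or 0.03 after quantile normalization), UBC21 (-0.07) and SAND (-0.13) had a median of -0.05 (percentile 40.3), between -0.08 and -0.01 over the alternatives. The flowering, nitrogen, phosphate, camalexin and heat shock lists (5 lists) were not analysed here, since no probe set was listed under their members alone.

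Of the 12 lists with a median, 3 lay outside the central 95% of random lists, where 0.6 would be expected by chance if genes varied independently. Genes of a list may vary together between plants, which 1 array per group cannot show. The 3 against 0.6 is therefore not evidence of an effect of the fungus. The ratio of signals from the 3' and 5' ends of a transcript is a sign of RNA integrity, and the array carries an older and a newer design of such probe sets. For actin it was 7.50 in controls and 8.08 with T. hamatum in the older design, and 1.70 on both arrays in the newer. The older actin probe sets carry unlike suffixes, so their ratio may not reflect RNA integrity alone. For ubiquitin the ratio of 3' to 5' signals was 1.96 and 2.42 in the older design, and 1.1 and 1.15 in the newer. For GAPDH it was 1.12 and 1.00 in the older design, and 0.846 and 1.02 in the newer. The 32 Affymetrix control probe sets above the floor had log2 ratios from -0.32 to 0.50, all within 2-fold. The highest was a 25S ribosomal RNA probe set (201 in controls and 285 with T. hamatum).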

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

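More probe sets were lower than higher under each alternative for which they were counted, while its size depended on the floor and on the added constant. Probe sets lower and higher by 2-fold numbered 106 and 12 as reported, and 105 and 13 without centring, 95 and 18 after quantile normalization and 103 and 13 without the lowess trend. They were not counted with the highest probe set of a locus, which changes only values per locus. They numbered 193 and 51 with the floor at the 25th percentile, 47 and 7 at the 60th, and 58 and 6 with 16 added to each signal. With probe sets of 1 gene alone, an alternative chosen after seeing the data, they were 46 and 7, as fewer probe sets entered. Probe sets bright on the control array alone numbered 6 as reported, 2 at the 25th percentile floor, 18 at the 60th and 2 with 1 gene alone; those bright on the T. hamatum array alone were 0 as reported and 2 at the 60th. For list medians, a move was judged against the half-width of the random lists' range. The phenylpropanoid and flavonoid median moved from -1.35 to -1.09 with 16 added, still at percentile 0, and the iron median from -0.15 to 0.18 with the 25th percentile floor, which admitted BHLH101. The other list medians moved by less than that half-width, and the 3 lists outside their ranges stayed outside in each alternative that gave a value. With the floor at the 60th percentile, the phenylpropanoid and flavonoid list, the early response list and some others kept fewer than 3 members. These gave no value, so of the 3 only the cell wall list was placed there (-0.24, percentile 1.86). Of 18 named genes past 2-fold, 15 stayed past it wherever they were measured and 0 changed sign. Several of them shrank with 16 added to each signal. Among these were AT1G15010 (log2 ratio -3.11 to -2.66), AT2G27080 (-2.67 to -2.30) and UGT75C1 (-1.62 to -1.27), which were not measured with the floor at the 60th percentile. Of 56 smaller values, 4 changed sign or reached 0 (ARR16, LHCB4.1, GSTU20 and the F-box gene). No paired analysis was possible because the groups share a single replicate number with 1 array each. Leaving out a replicate was likewise not possible. Log2 ratios spread more widely at low signal, with robust SDs of 0.26, 0.31 and 0.28 in the lowest 3 of 10 equal bins of measured level and 0.14 in the highest, and the floor sets how many of these low probe sets enter the counts.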

Other observations

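All tests in this part were chosen after the results were seen. Further genes past 2-fold fell outside the naming rule and were picked after their values were seen. Lower with T. hamatum were AT1G76960 (6.18-fold), OPCL1, an enzyme of jasmonate synthesis (2.17-fold), the U-box ubiquitin ligase PUB23 (2.30-fold), PR-1-LIKE (2.33-fold), SRC2 (2.01-fold) and the brassinosteroid acyltransferase BAT1 (2.06-fold). RAPTOR1, a component of the TOR kinase complex, was 2.02-fold lower. With T. hamatum, the signals of PR-1-LIKE (25.3) and AT1G76960 (30.4) were close to the floor of 24.5. Higher were AT2G15020 (2.36-fold), AT2G27420 (2.15-fold), AT5G59680 (2.09-fold) and AT1G60080 (2.04-fold), each with control signals near the floor.

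Of 15 gene groups added after the gene annotation was seen, 13 took the genes whose names share a stem, not whole families. Of the 15 groups, 1 lay outside the 95% range of matched random lists, where 0.75 would be expected by chance if genes varied independently. This was the serine carboxypeptidase-like group (SCPL), with a median log2 ratio of -0.16 over 14 genes (percentile 0.94), 9 of them below 0. It stayed outside under the other scalings, at -0.13 after quantile normalization. The 67 plastid-encoded genes had a median of 0.05 (percentile 70.0) and the 5 mitochondrion-encoded ones 0.10 (percentile 78.4). The beta-glucosidase genes named BGLU had a median of -0.18 over 9 genes (percentile 3.73). This group left out the beta-glucosidase PYK10 (0.22), which is named otherwise. The glycosyltransferase genes named UGT in the annotation had a median of -0.03 over 26 genes (percentile 30.5), which turned to 0.01 after quantile normalization. This group left out UGT75C1 (-1.62) and UF3GT (-1.08), which the annotation names otherwise. The ALDH (0.05), ATG (-0.04), BZIP (-0.15), CYP (-0.05), IQD (0.07), PRA (-0.08), TBL (-0.04, or 0.01 after quantile normalization), UBP (-0.15) and VPS (-0.11) groups had medians inside their ranges.

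The tables argue against scaling or dim signals as the whole cause of the excess of lower over higher probe sets. The ratio of lower to higher counts was 5.28 after quantile normalization and 7.92 without the lowess trend. The deposited values without centring differ from the centred ones by a constant alone, so they add nothing on scaling. Among probe sets at or above the median level the ratio of counts was 6.86 (48 against 7). How many of these probe sets differ by noise alone is not known without replicates. Plant samples that differed in something other than the fungus, such as handling at harvest, cannot be told apart from an effect of T. hamatum, because there was 1 array per group. The fungus remains an open and untested explanation.

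The lower signals of UGT75C1, DFR and UF3GT may be thought to follow from less green tissue in the T. hamatum sample. The photosynthesis list, which would then be lower too, had a median log2 ratio of 0.16, and 0.04 after quantile normalization, which argues against that. A difference in light, stress or age between the 2 plant samples cannot be told apart from the fungus with 1 array per group.

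Signal from PDF1.2b in the PDF1.2 probe set cannot be told apart from PDF1.2 transcript, because the value at hand, -3.98 in the probe set without the shared-probe suffix, is the pattern itself. GRX480 is known as a repressor of PDF1.2 when abundant. A hypothesis of repression through more GRX480 transcript would need a higher level with T. hamatum, and it was at -1.33, in the opposite direction. Whether the fungus or chance between plants could account for the defensin difference stays open and untested.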
